A study of Homo sapiens with 6 samples.

How the data were processed

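The series compared mRNA of H3122 cells, a human lung adenocarcinoma line known for a fusion of EML4 with the ALK receptor tyrosine kinase gene, with mRNA of a crizotinib-resistant derivative. Crizotinib is an inhibitor of the ALK and MET kinases. Per the labels' protocols, the resistant cells were raised by stepwise exposure to crizotinib from 0.1 to 10 µM, total RNA was extracted with TRIzol, poly(A) RNA was captured on beads, and libraries were made with a KAPA stranded mRNA kit for Illumina sequencing. There were 6 libraries, 3 control and 3 resistant. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

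The authors deposited 1 table of TPM (length-scaled transcript abundance that sums to 1000000 in a library) for 51537 genes, with a column per library. TPM divides the reads of a gene by its length and rescales each library, and each deposited column summed to 1000000. HISAT2 is named as a tool per the submitters' processing notes. Its version, the counting tool, the genome build, the annotation and any filter are not given in the sources used here. All 51537 gene identifiers occur in GENCODE release 29, and 51226 had a symbol in the name table used. Coordinates in the text are those of GENCODE 29 on GRCh38, 1-based; the build the authors used is not known.

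TPM keeps no depth. To estimate it, each TPM value was multiplied by the union exon length of the gene in GENCODE 29 and divided by the smallest step of the library. The result was a whole number within 0.01 read for 66.9% to 67.7% of the values above 0, and for 77.6% to 78.4% of those up to 100 reads. The rebuilt totals were 29856917 to 36695570 reads per library, and 1 TPM of a 2000 bp gene corresponded to 17.0 to 21.0 reads. These totals are estimates, because the lengths the authors used are not known and values that were not whole were kept as they were.

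The plan written before the data were examined named a test on counts first and limma on log2 values if the table held only TPM. The table held only TPM, so limma 3.58.1 in R 4.3.3 was the main test. Genes with at least 1 TPM in at least 3 libraries were kept, which left 16077. A linear model of log2(TPM + 1) on the group was fitted to all 6 libraries with empirical Bayes moderation, a mean-variance trend and robust estimation (statmod 1.5.0). Tests were two-sided. P-values were adjusted by Benjamini-Hochberg, and genes with an adjusted p below 0.05 were called changed. All log2 fold changes are resistant minus control on the log2(TPM + 1) scale, which understates the change of genes with low TPM. Adjusted p-values in the text are from this limma test unless another test is named.

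The text uses 54 gene lists written before the data were examined. Of their 1378 members, 1357 were found; most of the others were histone genes whose identifiers did not match. The 50 lists with at least 5 tested members were tested with camera of limma, with the preset inter-gene correlation of 0.01, and adjusted by Benjamini-Hochberg over the lists. Camera was repeated with an estimated correlation. Counts of changed members were also made with p-values adjusted over the list alone.

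Named genes were chosen by a rule fixed in advance. It took the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among called genes whose groups did not overlap, with a mean of at least 5 TPM in the higher group, not at 0 in all libraries of a group, and with a symbol that is not a clone, non-coding or antisense name. It added ALK, EGFR, MET, KIT, IGF1R, AXL, ABCB1, CDH1 and VIM whatever their result. For each list described it added up to 4 called members with a mean of at least 5 TPM in the higher group, largest absolute change first, or the most abundant member where fewer than 2 were called. Any other gene is said to have been chosen after its values were seen. The results of 2 genes that the rule takes are not reported here.

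Replicates were compared before they were averaged. A chi-square per gene on the rebuilt reads, over genes with at least 50 reads, was 2.44 to 5.59 within groups, above the value near 1 that counting noise gives, so no library was treated as a copy of another. The test was checked on 1 simulated table of 15728 tested genes made from the control means and the rebuilt totals, with 200 genes changed. It recovered 83.7% of the genes changed by 1 on the log2 scale and 49.5% of those changed by 0.5, with 0 in the wrong direction. Of the simulated calls, 12.7% were genes that had not been changed; 15 of these 19 genes had a mean under 30 reads. Among genes with at least 30 reads that share was 2.94%. The simulation changed far fewer genes than were called in the libraries (7815) and fixed the dispersion, so these shares may not carry over.

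Alternatives planned in advance were a pseudocount of 0.1, no filter on low values, median-ratio scaling of the libraries, the replicate number as a block, leaving out each library in turn, camera with an estimated correlation, fry, and camera without the 1% of genes with the largest mean. Chosen after seeing the data were limma-voom on the rebuilt reads, a minimum of 30 rebuilt reads on average, a filter at 5 TPM in 3 libraries, and rescaling to nuclear protein-coding genes. The comparison of fold changes by chromosome used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. It was tested on 9905 shuffled fold changes with the genes of chromosome 13 lowered by 0.5. Chromosome 13 was recovered and 0 of the 22 other chromosomes were called. Shuffling removes the correlation between neighbouring genes seen in the data, so this check cannot show how often such correlation gives false calls.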

Results

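Poly(A) RNA was profiled in 3 libraries of control H3122 lung adenocarcinoma cells and 3 libraries of crizotinib-resistant H3122 cells. The series title sets the question: how transcripts differ in cells that had become resistant to this ALK inhibitor, alongside metabolite measurements that are not analysed here. Each library had an estimated 29856917 to 36695570 reads, and 15485 to 16272 genes reached 1 TPM. Values below are TPM as mean ± SD with n = 3 per group, and log2 changes are resistant minus control with their standard error.

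ALK, the receptor targeted by crizotinib, was near the floor in all 6 libraries. ALK (ENSG00000171094, chromosome 2, 29192774 to 29921566) was at 0.250 ± 0.0858 TPM in the control libraries and 0.237 ± 0.0114 TPM in the resistant libraries. Single libraries lay between 0.154 and 0.32 TPM, with an estimated 9.63 to 21.4 reads each, so the gene was below the filter and was not tested. EML4, the fusion partner for which the line is known, was at 40.5 to 46.0 TPM in the control and 24.3 to 32.2 TPM in the resistant libraries. The libraries are therefore called by their labels, and the ALK fusion transcript itself was not measured here.

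The libraries separated by group. Of 50 gene lists tested with camera, 5 were called higher in resistant cells, those of interferon-stimulated genes, NF-kB and inflammatory cytokines, squamous and basal markers, mesenchymal markers and glycolysis, and 1, of goblet, mucin and gut-type markers, was called lower. These 6 calls were lost with an estimated correlation (adjusted p = 0.784 to 0.989). Of 16077 genes tested, 7815 were called changed by limma with Benjamini-Hochberg adjustment, 3852 higher and 3963 lower in resistant cells. At least a 2-fold change was seen for 596 higher and 366 lower genes. The first principal component held 66.0% of the variance. Pearson's r of log2 values, across genes that are not independent replicates, was 0.986 to 0.989 within groups and 0.957 to 0.960 between groups. The 2-fold counts depended on the setting: 977 higher and 553 lower with a pseudocount of 0.1, 1066 higher with limma-voom on rebuilt reads, and 313 higher and 234 lower with a filter at 5 TPM.

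Among genes that the naming rule takes, the largest increases included a transporter, inflammatory genes, a cytoskeletal linker and cancer-testis genes. SLC6A14 (ENSG00000268104, X, 116436622 to 116461458), an amino acid transporter, rose from 0.271 ± 0.160 to 49.0 ± 7.81 TPM (log2 5.30 ± 0.14, adjusted p = 8.28e-07). MSN (ENSG00000147065, X, 65588377 to 65741931), which encodes moesin, a linker of actin to the plasma membrane, rose from 38.3 ± 0.584 to 442 ± 13.1 TPM (log2 3.49 ± 0.04, adjusted p = 3.06e-08). LTB, which encodes lymphotoxin beta, rose from 0.325 ± 0.0286 to 16.5 ± 1.75 TPM. CXCL8, a neutrophil chemokine, rose from 1.52 ± 0.305 to 26.0 ± 4.02 TPM, and SAA1, an acute-phase protein gene, from 1.16 ± 0.788 to 27.2 ± 6.64 TPM. OAS2 and OASL, genes of the oligoadenylate synthetase family, rose from 0.421 ± 0.0921 to 12.7 ± 0.980 TPM and from 1.36 ± 0.399 to 20.6 ± 1.02 TPM. KRT6A rose from 0.580 ± 0.108 to 15.8 ± 1.37 TPM. SPANXB1 rose from 0.617 ± 0.386 to 20.9 ± 1.08 TPM and MAGEA1 from 0.680 ± 0.262 to 15.5 ± 0.609 TPM. SAA1, KRT6A, SPANXB1 and MAGEA1 have near-identical relatives, and how the authors' counting shared such reads is not known, so these 4 values are uncertain.

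Among genes that the naming rule takes, the largest decreases were, in this order, in an imprinted gene, a basement membrane collagen and a T cell receptor constant gene. A binding protein of insulin-like growth factors, a mucin and a gluconeogenic enzyme came next, also in order. The rule leaves out genes at 0 in all libraries of a group, such as TSPYL5 (13.1 TPM in control libraries), named after its values were seen. PEG10 (ENSG00000242265, chromosome 7, 94656325 to 94669695), a retrotransposon-derived imprinted gene, fell from 62.4 ± 2.55 to 0.208 ± 0.0867 TPM (log2 -5.72 ± 0.08, adjusted p = 8.17e-08). COL4A2 (ENSG00000134871, chromosome 13, 110305812 to 110513209), a chain of type IV collagen, fell from 21.2 ± 0.0988 to 0.135 ± 0.0374 TPM (log2 -4.29 ± 0.09, adjusted p = 3.74e-07). FBP1 (ENSG00000165140, chromosome 9, 94603133 to 94640249), a rate-limiting enzyme of gluconeogenesis, fell from 83.2 ± 2.56 to 5.45 ± 0.394 TPM. IGFBP5, which binds insulin-like growth factors, fell from 38.4 ± 2.26 to 1.11 ± 0.106 TPM. HCAR1, a lactate receptor, fell from 10.8 ± 0.434 to 0.0573 ± 0.0433 TPM, and SLC1A6, a glutamate transporter, from 8.47 ± 0.0477 to 0.0461 ± 0.0150 TPM. HSD3B1, a steroid-converting enzyme, fell from 18.9 ± 1.51 to 1.36 ± 0.415 TPM. TRBC2, a T cell receptor constant gene with a near-identical neighbour and thus uncertain, fell from 33.1 ± 3.49 to 0.790 ± 0.307 TPM. SLURP1 fell from 8.62 ± 1.90 to 0.134 ± 0.116 TPM on an estimated 22.3 reads per library. The median log2 change over 153 protein-coding genes with a mean of at least 5 TPM was -0.59 on chromosome 13, and that over 456 such genes was -0.34 on chromosome 7, so PEG10 and COL4A2 lie on chromosomes whose genes were lower as a group.

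**Figure D1:**
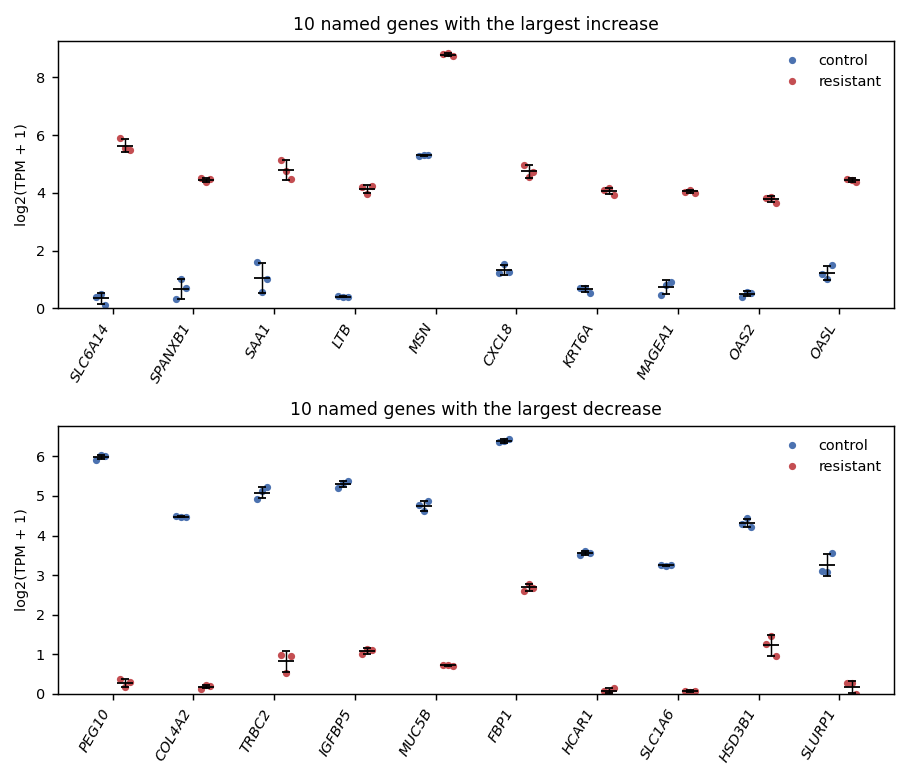
Expression as log2(TPM + 1) of the 10 named genes with the largest increase (top) and the 10 with the largest decrease (bottom); each point is a library, blue for control and red for resistant, and black bars are the mean and SD of 3 libraries. For each gene the 3 libraries of a group lie apart from those of the other group, as for SLC6A14, with means of 0.271 and 49.0 TPM.

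Interferon-stimulated genes rose as a group. Of 31 tested members, 26 rose, 1 fell and 4 did not pass the test, and 17 rose at least 2-fold; adjusted over the list alone, 27 rose and 1 fell. Besides OAS2 and OASL, IFI44 rose from 0.356 ± 0.171 to 9.30 ± 0.825 TPM and IFI6, a mitochondrial survival factor of the interferon response, from 23 ± 1.65 to 139 ± 8.70 TPM. The member that fell was SAMD9 (log2 -2.31), an antiviral factor on chromosome 7 named after its values were seen. The median log2 change of the list was 1.06 (camera adjusted p = 7.24e-10; adjusted p = 0.784 with an estimated correlation).

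NF-kB and inflammatory cytokine genes rose as well. Of 22 tested members, 19 rose and 3 fell, with the same counts adjusted over the list alone, and 12 rose at least 2-fold. CXCL1, another neutrophil chemokine, rose from 0.423 ± 0.287 to 11.8 ± 0.865 TPM. SAA2, a near-identical relative of SAA1 and thus uncertain, rose from 0.0769 ± 0.0446 to 5.20 ± 1.21 TPM. The median log2 change was 1.09 (camera adjusted p = 4.73e-07; adjusted p = 0.784 with an estimated correlation). Immune cell markers were low in these libraries: 18 of 22 were under 1 TPM in all 6, and the median marker was at 0.0751 TPM in control and 0.158 TPM in resistant libraries. Of 18 tested MHC class I genes, 10 rose and 1 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.0694), and HLA-B, whose reads are shared between HLA genes and thus uncertain, rose from 4.66 ± 0.834 to 14.9 ± 1.09 TPM. TAP2, a peptide transporter, rose from 11.9 ± 0.375 to 18.4 ± 0.992 TPM. The MHC class I list passed without a filter on low values (adjusted p = 0.0223) and with limma-voom on rebuilt reads (adjusted p = 0.018). Of 21 tested complement and coagulation genes, 12 rose and 4 fell (13 and 5 adjusted over the list alone; camera adjusted p = 0.106), and the list passed with a filter at 5 TPM (adjusted p = 0.018). C3, the central complement component, rose from 10.1 ± 0.389 to 47.5 ± 2.55 TPM, while TFPI2, a protease inhibitor, fell from 30.9 ± 2.12 to 13.7 ± 0.409 TPM.

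Squamous and basal markers rose and mucin markers fell. Of 16 tested squamous and basal markers, 11 rose, 2 fell and 3 did not pass, with the same numbers rising and falling adjusted over the list alone (median log2 1.03; camera adjusted p = 0.00252; adjusted p = 0.784 with an estimated correlation). KRT13, a keratin of stratified epithelium, rose from 1.87 ± 0.286 to 13.5 ± 1.07 TPM. SPRR1B, a cornified envelope precursor, rose from 1.43 ± 0.166 to 8.56 ± 1.38 TPM on an estimated mean of 29.2 reads per library. KRT6B, a close relative of KRT6A and thus uncertain, rose from 0.414 ± 0.242 to 6.39 ± 1.74 TPM. The 2 members that fell, named after their values were seen, were SOX2 (log2 -1.69) and KRT17 (log2 -1.26). Of 9 tested goblet, mucin and gut-type markers, 6 fell and 1 rose, also adjusted over the list alone (median log2 -0.58; camera adjusted p = 0.0128; adjusted p = 0.784 with an estimated correlation). MUC5B, a gel-forming airway mucin, fell from 26.0 ± 2.37 to 0.652 ± 0.0132 TPM, AGR2, which folds mucins, from 105 ± 14.3 to 25.1 ± 1.95 TPM, BPIFB1, a secreted airway protein, from 64.9 ± 6.42 to 18.5 ± 0.719 TPM, and SPDEF, a goblet cell transcription factor, from 64.6 ± 7.87 to 24.9 ± 1.13 TPM. The call of this list was lost without a filter on low values (adjusted p = 0.0663) and with a filter at 5 TPM (adjusted p = 0.0521).

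Mesenchymal markers rose as a list while vimentin stayed near 0. Of 15 tested members, 11 rose and 3 fell, with the same counts adjusted over the list alone (median log2 0.41; camera adjusted p = 0.00794; adjusted p = 0.951 with an estimated correlation); another list holds 13 of its 30 members. The members with the largest change were matrix genes: COL6A2 rose from 4.01 ± 0.747 to 15.7 ± 0.505 TPM, COL1A1 from 3.97 ± 0.261 to 13.8 ± 0.753 TPM and COL6A1 from 24.9 ± 0.545 to 55.6 ± 2.45 TPM, while TNC, which encodes the matrix protein tenascin C, fell from 7.69 ± 0.317 to 2.12 ± 0.287 TPM. Some members outside the matrix also changed and are named after their values were seen. CDH2, which encodes N-cadherin (log2 1.10), SNAI1 (0.41) and TWIST2 (0.31) rose, while S100A4 (-0.86) and TAGLN (-0.76) fell. VIM was at 0.00739 ± 0.0128 and 0.0219 ± 0.0222 TPM. CDH1, which encodes the epithelial adhesion protein E-cadherin, rose from 182 ± 5.41 to 234 ± 6.33 TPM (log2 0.36 ± 0.04, adjusted p = 3.68e-04). Of 27 tested epithelial markers, 5 rose and 11 fell, and the list was not called (5 and 12 adjusted over the list alone; camera adjusted p = 0.415); EPCAM fell from 319 ± 25.1 to 248 ± 2.97 TPM and CDH3 rose from 87.3 ± 3.72 to 144 ± 5.11 TPM. Fibroblast markers were at a median of 0 TPM in control and 0.01 TPM in resistant libraries, and endothelial markers at 0.0435 and 0.101 TPM. In all 6 libraries, 12 of 14 fibroblast and 9 of 13 endothelial markers were under 1 TPM. COL1A1 is also a fibroblast marker, and some markers were well expressed. FBLN1 was at 387 TPM in control and 292 TPM in resistant libraries, and the endothelial marker EGFL7 at 65.0 and 75.5 TPM. Collagens, laminins and integrins went both ways: 16 of 31 rose and 8 fell (16 and 9 adjusted over the list alone; camera adjusted p = 0.114). That list passed without a filter on low values (adjusted p = 0.0205). Besides COL4A2, COL12A1 fell from 39.3 ± 0.937 to 13.5 ± 0.180 TPM, while the laminin chains LAMA3 and LAMA4 rose from 3.97 ± 0.291 to 17.4 ± 1.93 TPM and from 7.05 ± 0.339 to 20.5 ± 0.971 TPM.

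**Figure D2:**
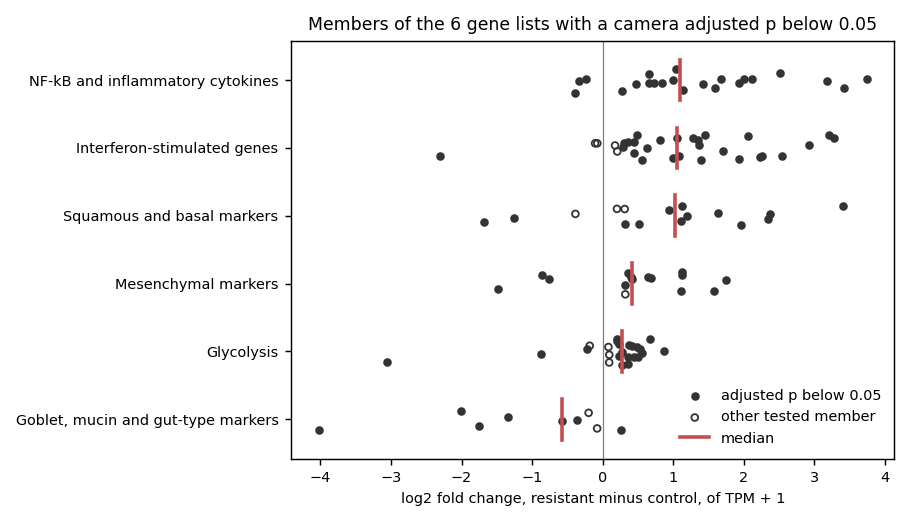
Log2 fold change, resistant minus control, of TPM + 1 for each tested member of the 6 lists called by camera with the preset correlation; filled points had an adjusted p below 0.05, open points did not, red lines are list medians and height within a list carries no meaning. Medians lie above 0 for 5 lists, up to 1.09 for NF-kB and inflammatory cytokines, and at -0.58 for goblet, mucin and gut-type markers.

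Receptor tyrosine kinases that can act beside ALK were measured next. AXL rose from 7.15 ± 0.129 to 22.1 ± 0.494 TPM (log2 1.5 ± 0.06, adjusted p = 3.31e-06), and EGFR from 193 ± 1.64 to 243 ± 3.60 TPM (log2 0.33 ± 0.04, adjusted p = 2.54e-04). IGF1R fell from 16.2 ± 0.0874 to 10.1 ± 0.728 TPM (log2 -0.63 ± 0.07, adjusted p = 2.38e-04). MET was at 46.2 ± 3.92 and 39.3 ± 4.64 TPM, a difference that did not pass the test (log2 -0.23 ± 0.09, adjusted p = 0.0802) but did pass with median-ratio scaling (adjusted p = 0.0363), with nuclear protein-coding rescaling (adjusted p = 0.0247), with at least 30 rebuilt reads (adjusted p = 0.0429) and without resistant replicate 1 (adjusted p = 0.0148) or control replicate 1 (adjusted p = 0.0380). MET and EGFR lie on chromosome 7, where the median log2 change over 456 expressed protein-coding genes was -0.34. The change of MET was thus no larger than that of its chromosome. KIT was listed at 0 in all 6 libraries. Of 17 tested members of the receptor list, 11 rose and 5 fell (11 and 6 adjusted over the list alone; camera adjusted p = 0.235). FGFR4 rose from 3.54 ± 0.358 to 8.25 ± 0.0287 TPM and EPHA2 from 62.6 ± 0.840 to 123 ± 8.21 TPM, while FGFR3 fell from 93.9 ± 2.48 to 38.3 ± 2.75 TPM.

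Receptor ligands and ERK pathway output genes were lists that camera did not call. Of 15 tested ligands, 9 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.0550). The EGFR ligands HBEGF, AREG and EGF rose from 3.68 ± 0.818 to 13 ± 1.35 TPM, from 1.61 ± 0.158 to 5.46 ± 0.443 TPM and from 3.77 ± 0.324 to 9.61 ± 0.652 TPM, and VEGFC, a lymphatic growth factor, from 10.9 ± 0.969 to 24.0 ± 0.717 TPM. The ligand list passed with at least 30 rebuilt reads (adjusted p = 0.0486) and without control replicate 1 (adjusted p = 0.0400), control replicate 3 (adjusted p = 0.0451) or resistant replicate 1 (adjusted p = 0.0460). Of 25 tested ERK output genes, 8 rose and 12 fell, also adjusted over the list alone (camera adjusted p = 0.545). EGR1, an immediate early transcription factor, fell from 56.1 ± 4.54 to 17.9 ± 2.42 TPM and SPRY1, a feedback inhibitor of the pathway, from 6.73 ± 0.268 to 2.94 ± 0.494 TPM, while LIF, a cytokine, rose from 21.7 ± 0.938 to 49.0 ± 2.08 TPM.

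**Figure D3:**
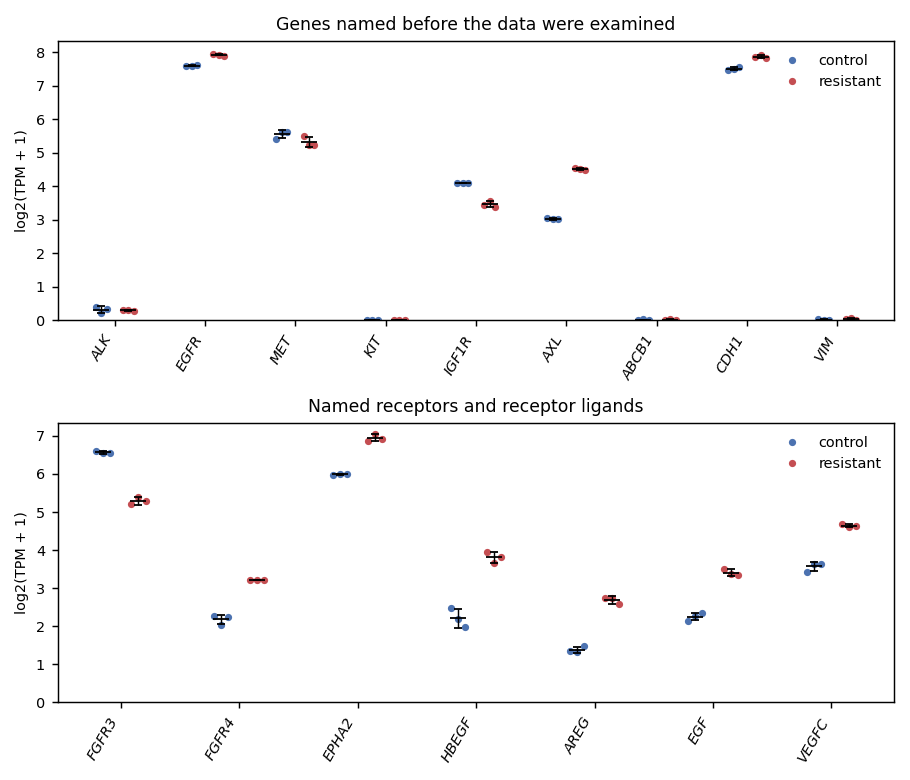
Expression as log2(TPM + 1) of the 9 genes named before the data were examined (top) and of named receptors and receptor ligands (bottom); each point is a library, blue for control and red for resistant, and black bars are the mean and SD of 3 libraries. AXL lies higher in resistant libraries (22.1 against 7.15 TPM), and ALK, KIT, ABCB1 and VIM lie near 0 in both groups.

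Among 12 tested ABC drug transporters, 4 fell and the other 8 did not pass the test, also adjusted over the list alone (camera adjusted p = 0.323). ABCC4, an efflux transporter of nucleotides and drugs, fell from 49.3 ± 3.25 to 12.7 ± 0.176 TPM, and ABCC3 from 258 ± 10.2 to 191 ± 8.36 TPM. ABCC4 (log2 -1.88) lies on chromosome 13, where the median over 153 expressed protein-coding genes was -0.59. ABCB1, the multidrug transporter P-glycoprotein, was at 0.00708 ± 0.0123 and 0.0128 ± 0.0111 TPM, close to 0 reads, so a difference was not detectable at this depth. Among genes of xenobiotic metabolism, 7 of 17 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.813); CES1, a carboxylesterase, rose from 49.3 ± 4.11 to 325 ± 25.5 TPM and ALDH1A1, an aldehyde dehydrogenase, fell from 118 ± 12 to 59.0 ± 2.04 TPM.

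Glycolysis genes rose by small amounts, with exceptions. Of 24 tested members, 17 rose and 3 fell (18 and 4 adjusted over the list alone; median log2 0.28; camera adjusted p = 0.00794; adjusted p = 0.989 with an estimated correlation). ALDOC, an aldolase, rose from 20.4 ± 0.600 to 38.2 ± 0.785 TPM and LDHB, a lactate dehydrogenase subunit, from 21.9 ± 0.837 to 35.7 ± 2.23 TPM. SLC2A3, a glucose transporter, fell from 9.18 ± 0.552 to 0.226 ± 0.0653 TPM, and PGK1, a glycolytic kinase on the X chromosome, from 423 ± 17.4 to 231 ± 8 TPM; the median over 318 expressed X-linked protein-coding genes was -0.35. The call was lost when the 1% of genes with the largest mean was left out (adjusted p = 0.0535).

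Other metabolic lists held members that went both ways and were not called by camera. Of 24 TCA cycle genes, 4 rose and 10 fell (camera adjusted p = 0.235), and IDH1 fell from 241 ± 14.3 to 164 ± 7.62 TPM while ACO1, an aconitase, rose from 42.5 ± 3.02 to 60.5 ± 1.25 TPM. Of 26 tested sphingolipid genes, 4 rose and 11 fell (5 and 11 adjusted over the list alone; camera adjusted p = 0.266): CERS4, a ceramide synthase, fell from 72.9 ± 3.72 to 31.1 ± 1.40 TPM, SGMS1, a sphingomyelin synthase, from 38.0 ± 3.25 to 16.8 ± 0.0686 TPM, and SGPL1, which degrades sphingosine phosphate, from 103 ± 2.70 to 48.1 ± 2.62 TPM. Of 25 purine genes, 9 rose and 6 fell (camera adjusted p = 0.544); XDH, xanthine dehydrogenase, rose from 8.33 ± 0.653 to 30.3 ± 1.56 TPM and IMPDH1, of guanine nucleotide synthesis, fell from 179 ± 2.91 to 91.4 ± 2.24 TPM. Of 23 tested cholesterol synthesis genes, 12 rose and 4 fell (camera adjusted p = 0.223), and LSS, lanosterol synthase, rose from 28.2 ± 0.492 to 43.5 ± 1.5 TPM. Of 16 tested arachidonate genes, 5 rose and 7 fell (camera adjusted p = 0.995), and the largest changes went both ways. PLA2G10, a secreted phospholipase with a related pseudogene and thus uncertain, fell from 7.32 ± 3.33 to 1.63 ± 0.251 TPM, and HPGD, which degrades prostaglandins, from 12.4 ± 1.74 to 4.84 ± 0.223 TPM. The cytochrome P450 genes CYP4F3 and CYP4F11 rose from 16.1 ± 0.599 to 46.0 ± 2.36 TPM and from 111 ± 2.08 to 228 ± 3.78 TPM. TCA, purine, cholesterol and arachidonate counts were the same adjusted over the list alone. Of 43 nuclear OXPHOS genes, 7 rose and 7 fell (6 and 7 adjusted over the list alone; camera adjusted p = 0.8).

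Proliferation genes went both ways and p53 target genes included a few large increases. Of 28 proliferation genes, 10 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.430); CDK1, the mitotic kinase, rose from 125 ± 10.5 to 197 ± 20.7 TPM, while CENPF, which encodes a kinetochore protein, fell from 72.2 ± 10.8 to 49.6 ± 9.84 TPM (adjusted p = 0.0297). The call of CENPF was lost without a filter on low values (adjusted p = 0.0606), and without control replicate 2 (adjusted p = 0.0841) or 3 (adjusted p = 0.0650) or resistant replicate 2 (adjusted p = 0.0721) or 3 (adjusted p = 0.0814). Of 23 tested p53 targets, 10 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.235); CDKN1A, which encodes the cell cycle inhibitor p21, rose from 24.0 ± 1.32 to 90.0 ± 5.35 TPM and TP53INP1 fell from 9.95 ± 1.47 to 2.39 ± 0.449 TPM. Of 20 tested BCL2 family and related genes, 4 rose and 7 fell (6 and 8 adjusted over the list alone, camera adjusted p = 0.822). BCL2L11, which encodes the pro-apoptotic protein BIM, fell from 22.7 ± 1.25 to 14.4 ± 0.597 TPM. BCL2L1, which encodes the anti-apoptotic protein BCL-XL, rose from 89.4 ± 5.36 to 129 ± 5.36 TPM. XIAP and CFLAR, which encode other inhibitors of apoptosis, fell from 40.3 ± 1.54 to 26.3 ± 2.34 TPM and from 23.2 ± 1.17 to 17.2 ± 0.470 TPM. Of 25 tested TGF-beta targets, 6 rose and 10 fell (8 and 10 adjusted over the list alone; camera adjusted p = 0.567); BMP4, a growth factor, rose from 2.97 ± 0.232 to 21.2 ± 2.14 TPM and ID1, a transcriptional inhibitor, from 51.4 ± 2.52 to 246 ± 20.3 TPM, while COL4A2, the member with the largest change, and SMAD6, an inhibitory SMAD, fell, SMAD6 from 29.8 ± 1.65 to 13.1 ± 0.538 TPM. Of 17 tested Wnt and Notch targets, 5 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.995), and DKK1, a Wnt antagonist, fell from 124 ± 7.82 to 22.8 ± 0.629 TPM, while HES4, a transcription factor, rose from 53.8 ± 2.23 to 105 ± 7.81 TPM.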

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

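The alternatives of limma-voom on rebuilt reads, at least 30 rebuilt reads, a filter at 5 TPM in 3 libraries and nuclear protein-coding rescaling were chosen after the data were seen. No gene was called in opposite directions under the main test and any alternative. Total calls ranged from 6458 to 8741 around the main 7815. Leaving out each library in turn gave 6458 to 7475 changed genes and kept 80.9% to 89.3% of the main calls, with 3316 to 3604 higher, 3114 to 4042 lower, 573 to 626 higher and 332 to 413 lower at least 2-fold, and 5 to 6 lists higher and 1 lower. The 2-fold counts, 596 and 366 in the main test, were 977 and 553 with a pseudocount of 0.1, which shrinks low genes less, 1066 higher with limma-voom on rebuilt reads, where the cause was not tested, and 313 and 234 with the 5 TPM filter, which tested fewer genes. The main test called 5 lists higher and 1 lower. Camera with an estimated correlation called 0 and 0, with 2 of the 50 lists, both higher, at an unadjusted p below 0.05, and fry, which does not compare a list with other genes, called 21 and 5. By camera, 7 lists were higher and 0 lower with no filter on low values (MHC class I and collagens gained, mucin markers lost at adjusted p = 0.0663), 7 and 0 with the 5 TPM filter (complement and matrix proteases gained, mucin markers lost at adjusted p = 0.0521) and 7 and 1 with limma-voom (MHC class I and matrix proteases gained); the cause was not tested. The replicate block gave 6856 changed genes (84.9% of the main calls kept); the deviations of same-numbered libraries correlated at -0.31, -0.08 and 0.04, so the numbers are not taken as pairs. Count-based alternatives of the plan (other count scalings and filters, and other count tools) were not run because the table holds TPM. Calls of genes with few reads are less certain, since most false calls on simulated data had under 30 reads. With at least 30 rebuilt reads on average, 7844 of 13532 tested genes were called. Of these, 7205 were also called in the main test, which tested 16077 genes and called 7815. The sets of tested genes differed, so the similar totals do not show whether calls of genes with few reads are sound.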

Other observations

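In this part, the tests of the splits of the libraries, of ALK, of the share of chromosome 13 genes below 0, of immune cell RNA and of gene dosage in the interferon and NF-kB lists were chosen after their results were seen, as was the comparison by chromosome itself.

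A few genes went from expressed to near absent or the reverse. In 7 protein-coding genes all control libraries were at 5 TPM or more and all resistant libraries under 0.5 TPM, and 6 showed the opposite. Genes named here were chosen after their values were seen. TSPYL5, a nucleosome assembly protein family member, was at 13.1 TPM in control libraries and listed at 0 in all 3 resistant libraries. IFI16, a DNA sensor of the interferon response, rose from 0.0491 to 6.99 TPM, TREM1, an amplifier of inflammation, from 0.101 to 6.86 TPM, and the kinase gene AATK from 0.352 to 5.75 TPM. Cancer-testis genes moved in opposite directions: MAGEA1 and SPANXB1 rose while MAGEA3 fell from 92.2 ± 7.44 to 18 ± 2.66 TPM and MAGEA6 from 199 ± 13.3 to 126 ± 4.02 TPM (n = 3 per group). These families share near-identical sequence, so the split between their members is uncertain. Of 7 tested cancer-testis genes, 2 rose and 3 fell, also adjusted over the list alone; the list median was -0.43, its mean 0.41 and its camera adjusted p 0.870, so median and mean differ in sign.

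Metallothionein and metal-handling genes included 3 that rose and 5 that fell among 16 tested (6 and 5 adjusted over the list alone; median log2 0.10, mean -0.15, which differ in sign; camera adjusted p = 0.995). MT2A, a metal-binding protein gene, fell from 898 ± 24.7 to 487 ± 16.8 TPM and FTL, a ferritin chain, rose from 12100 ± 816 to 16990 ± 847 TPM. Among 16 heat shock genes, 8 rose and 4 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.235), and HSPB8, a small heat shock protein, rose from 8.36 ± 0.562 to 30.9 ± 2.25 TPM while HSPB1, another, fell from 2272 ± 19.5 to 1591 ± 125 TPM.

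Fold changes were grouped by chromosome. Over 9905 protein-coding genes with a mean of at least 5 TPM, the median log2 change was -0.59 on chromosome 13 (153 genes, 88.2% called lower), -0.34 on chromosome 7 and -0.35 on X, against 0.27 on chromosome 21; each had an adjusted p of 0.00023 from 10000 permutations of genes, whose smallest possible p is 0.0001, and 14 of 23 chromosomes passed 0.05. Genes are not independent replicates, and the permutations ignore the correlation between neighbours, so these p-values may be too small. Neighbouring genes correlated at r = 0.29 across genes, against at most 0.04 in 1000 shuffled orders. The lowest runs of 25 genes (GENCODE 29, GRCh38) were X from 65588377 to 77786233 (median -0.98), chromosome 1 from 45786987 to 51878937 (-0.93), a second run on chromosome 1 (-0.91) and chromosome 7 from 87152361 to 94669695 (-0.90), below the lowest of 200 shuffles (-0.55). MSN, the first gene of the X run, rose. TFPI2 and PEG10, which fell, lie in the chromosome 7 run. A run on chromosome 10 from 49818279 to 68212017 had a median of -0.83 and holds SGMS1 and DKK1, which fell. The highest run was chromosome 1 from 205142505 to 209806175 (0.53), above the highest of 200 shuffles (0.39). Chromosomes 7, 13 and X held 9.36% of these genes, 19.7% of the lower calls and 4.07% of the higher calls.

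For chromosome 13, the tables argue against GC content and length bias as the whole cause, since the median stayed at -0.503 after the trend on transcript GC and length was removed (95% bootstrap interval over genes -0.579 to -0.455). A few regulated genes do not account for it either, since 95.42% of the genes had a change below 0. With the genes split into 3 equal sets of low, middle and high mean TPM, the medians were -0.63, -0.47 and -0.62, the highest being -0.467. Fewer copies of the chromosome in the resistant cells would give this. With 95.42% of the genes below 0, however, the split had little room to come out otherwise, so it adds no support. A difference in chromosome 13 copies between the groups may be a candidate explanation. The values are relative, so a loss in resistant cells cannot be told from a gain in control cells. DNA was not measured here, and the hypothesis was found on the same libraries. After the same correction the median was -0.336 on chromosome 7, -0.347 on X and 0.297 on chromosome 21; before it, 78.3%, 74.8% and 15.6% of their genes had a change below 0, and the split by mean TPM was made for chromosome 13 only.

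ALK was near the floor in all 6 libraries. A short ALK part of a fusion transcript does not bring the values together: after scaling ALK to exons 20 to 29 (2141 of 7362 bp), the ratio of ALK to EML4 TPM was at most 0.034. Loss of fusion reads before the table was made and cells without the fusion transcript could both give this and cannot be told apart, because the table holds a mean of only 16.9 estimated reads for ALK per library and ALK was under 1 TPM in 6 libraries. The low level was in both groups, so it does not by itself separate resistant from control cells.

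Interferon and NF-kB genes rose together, though the camera calls of both lists were lost with an estimated correlation (adjusted p = 0.784). RNA from immune cells is argued against, since the median immune cell marker was at 0.158 TPM in the resistant libraries, with CSF1R (3.03 TPM in control and 5.13 TPM in resistant libraries) and CD14 (4.24 and 4.65 TPM) the most abundant, and LYZ and TYROBP listed at 0. Gene dosage of whole chromosomes is argued against by size alone. Chromosome medians over genes with a mean of at least 5 TPM lay between -0.59 and 0.27. The mean log2 change of 53 genes of both lists was 1.20. Subtracting chromosome medians could therefore move this mean little (1.208, SD 1.14, after it). The 45 genes called higher were on 15 chromosomes. Dosage of shorter segments was not tested. An inflammatory and interferon transcript programme of the carcinoma cells themselves may be a hypothesis left open; no upstream cytokine or pathway was tested.

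Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many changed genes as the real split, which is the real split itself (7815); the highest of the others gave 0 by limma, with 146 to 738 genes at an unadjusted p below 0.05 against 8888 in the real split. With 10 splits the share can never be under 0.1, so the splits are too few for a share under 0.05.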
